A study of Mus musculus with 23 samples.

How the data were processed

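Genomic DNA of GFP-positive leukemic marrow from transduced mice was compared with DNA of non-leukemic marrow on Agilent copy number arrays. Per the labels, the strain was C57BL/6, DNA was extracted with phenol and chloroform, and 1.5 ug was labelled with the Agilent ULS kit. Cy5 marked the leukemia and Cy3 the reference on each array, and no dyes were swapped, so a probe-specific dye bias does not cancel against the reference. The reference was mixed-sex marrow on 18 arrays and male marrow on 5.

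The arrays were processed with Agilent Feature Extraction 10.7.3.1 per the file headers, while the submitters' processing notes name version 10.5.1.1. Per the file headers the protocol subtracted the background, removed spatial trends and normalized the dyes by lowess. The deposited LogRatio column is the log10 of Cy5 over Cy3 of these processed signals. Per the file headers the processed, spot and background signal columns are linear intensity values. The deposited value table holds log2 Cy5 over Cy3, as a comparison with the scanner ratios showed, and it keeps the last spot of each probe (lowest correlation 1.0, largest difference 5e-05). Its scale and direction are thereby known, and it was not centred. Its column medians ran from -0.0051 to 0.009. Positions are on mm9 per the file headers, and the 2 arrays on slide 8 name no build but have identical positions.

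Main values were the log10 ratios turned to log2, with spots of one probe averaged and each array centred on its autosomal median. Of 402346 distinct probes, 382487 were autosomal, 19253 on X and 606 on Y, and the median spacing was 5.34 kb. No loess or quantile step was added. The normexp alternative started from the median spot signals, so it also lacks the lowess and spatial steps of the protocol. Its results differ from the main ones by more than the background correction. Median red signals ranged from 62.2 to 549 and green from 78.9 to 164. The red signal-to-noise ratio was lowest in MN1-FLI1 replicate 1 (7.64), and the green one in GATA2-HOXA9 replicate 5 (17.8). The number of arrays limits the precision. The files used here pair no probe with a gene, so the planned gene-level tests were run on 100 kb windows (means of their probes), and the tests of gene lists and of antigen receptor loci and the GC correction were not run. This departs from the plan made before the data were examined.

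limma 3.58.1 in R 4.3.3 was fitted to the 23 arrays in 6 groups with eBayes. A call needed an adjusted p under 0.05 (Benjamini-Hochberg) and a mean log2 ratio of at least 0.2 in size. Named windows are the 10 with the largest size per direction and comparison, 1 per run of calls within 1 Mb. The chromosome 5 probes, the single events and the gains on chromosomes 12, 14 and 6 were singled out after their values were seen. Segments came from a circular binary segmentation written for this work (change statistic 7, at least 3 probes per change, smallest step 0.1), in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. Called segments had at least 10 probes and a mean of at least 0.25. Matching segments in 12 or more arrays under 5 Mb were set apart as common, while pieces of these regions that match fewer arrays stayed in the counts. Of 370 called segments 113 were common. Group tests used 100000 resamples, or all 252 splits for a pair. Bright probes are those over 2 times the array median in the reference channel, 13885 in number, or 6261 at 3 times.

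On simulated data, limma recovered 95 of 100 windows changed by 0.3 and 99 of 100 changed by 0.6 for MN1 against the reference, and 88 and 98 of 100 for MN1-FLI1 against MN1, over 23629 windows. For the NIPBL probes it recovered 197 of 200 changed by 1.0. Segments of 20, 100 and 500 probes with a log2 ratio of -0.8 or 0.5 were recovered in 22 or 23 of 23 arrays. Smaller sizes, down to the calling height, and segments of fewer than 20 probes were not simulated. The recovery thus does not cover such segments, which are among those counted per leukemia. False calls numbered 2 for MN1 against the reference, 8 for MN1-FLI1 against MN1 and 13 for the NIPBL probes. The simulated noise was independent between windows or probes. It held no bright-probe losses and no single outlying spots, so these values do not cover calls from such sources. Alternatives were normexp background correction (offset 50, on median signals, as no mean signal was used here), centring on all probes or on the mode, the deposited value table, other window sizes and size floors, array weights, blocks for slide, scan day, reference and replicate number, and leaving out each array. Windows of 50 and 500 kb, the bright-probe settings, the scan-day subsets, joined segments, the removal of pieces of common regions, scan day as a block for the transgene probes, and the sets without the 7 arrays with a lowered X or the 11 whose X goes against the label were added after seeing the data.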

Results

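The series holds 23 two-colour genomic DNA arrays of mouse leukemias. Acute megakaryoblastic leukemia (AMKL) is a leukemia of the platelet lineage, and its fusion genes were put into mouse marrow to ask whether each one drives disease. On each array the Cy5 channel held DNA of leukemic marrow that carried a human transgene, and the Cy3 channel held DNA of non-leukemic marrow. A log2 ratio above 0 therefore means more DNA in the leukemia. There were 5 arrays each for MN1, NIPBL-HOXB9, GATA2-HOXA9 and MN1-FLI1, 2 for HOXB9 alone and 1 for FLI1 alone. MN1 is a transcriptional coregulator, NIPBL loads cohesin onto DNA, HOXA9 and HOXB9 are homeobox factors, GATA2 is a zinc-finger factor and FLI1 an ETS factor. All coordinates are those of the mm9 build. The labels say that the mice were wildtype or had an altered Ikzf1 gene, but not which mouse was which. The autosomes carried 382487 probes, and the noise between adjacent probes ranged from 0.149 to 0.356, with the highest value in MN1-FLI1 replicate 1. The number of arrays limits the precision of every group comparison, and p-values measure the spread between these arrays.

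The first comparison set the X and Y chromosomes of each array against the labelled sexes. Of the 18 arrays with a mixed-sex reference, all labelled female, 10 had a raised X chromosome and 7 a lowered one. These 7 arrays were MN1 replicates 1, 2, 4 and 5, GATA2-HOXA9 replicate 3, MN1-FLI1 replicate 3 and the FLI1 array. Their Y medians lay between 0.41 and 0.91. MN1 replicate 3 had an X median of 0.34 and a Y median of -2.19. NIPBL-HOXB9 replicate 4 was intermediate, with an X median of 0.09 and a Y median of -0.39. All 5 arrays with a male reference had X medians near 0, between -0.02 and 0.06, and 4 of them are labelled female, which should raise X. In these 4, NIPBL-HOXB9 replicate 2, GATA2-HOXA9 replicates 1 and 4 and HOXB9 replicate 1, the Y medians were -0.02, -0.14, -2.75 and -0.36. X was thus lowered over a mixed-sex reference, or not raised over a male one, in 11 arrays labelled female. Counting NIPBL-HOXB9 replicate 4, whose X was not raised over 0.1 either, makes 12. In its Cy5 channel the X signal was 0.740 and the Y signal 0.231 of the autosomal signal, between those of the arrays with a raised and a lowered X. In the Cy5 channel of the 11 arrays the X signal was 0.472 to 0.477 in the 4 with a male reference and 0.454 to 0.575 in the 7 with a lowered X. It was 0.872 to 0.942 in the 10 with a raised X. All labels are kept throughout, and the comparisons use the autosomes alone.

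**Figure D1:**
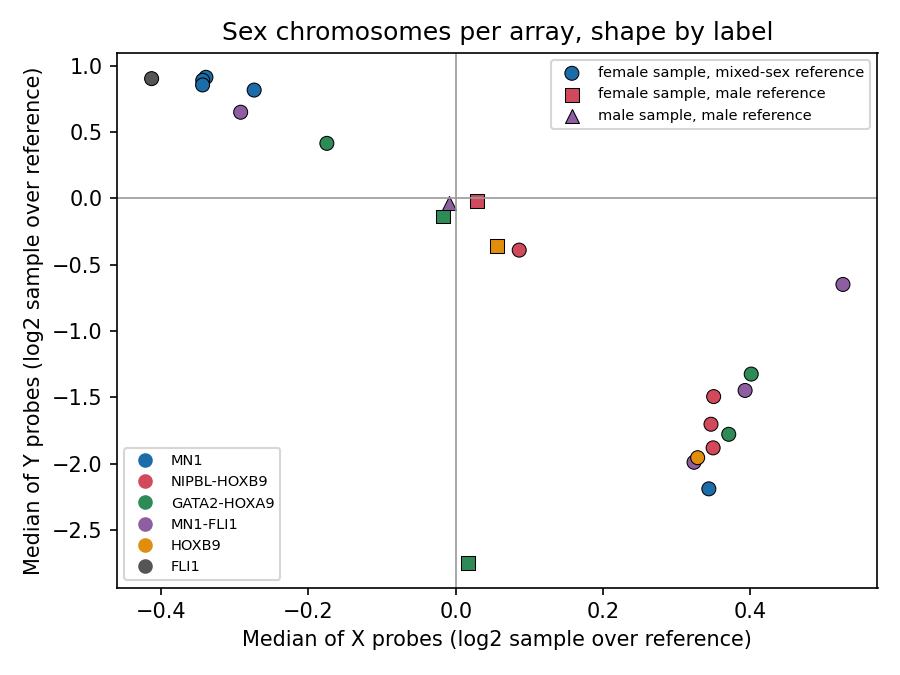
Median log2 ratio of the X probes (x axis) against that of the Y probes (y axis), 1 point per array, with colour for the group and shape for the labelled sexes. The 7 arrays at the upper left, with Y medians of 0.41 to 0.91, are labelled female.

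Large changes in single leukemias were examined next, to find chromosomes or arms that tumours of a transgene share. Chromosome 2 was lost over long stretches in 4 leukemias. The losses ran from 50741299 to 119936545 in GATA2-HOXA9 replicate 4 (69.2 Mb, mean log2 ratio -0.84), and from 61672706 to 174784030 in GATA2-HOXA9 replicate 2 (113 Mb, -0.84). They ran from 91233666 to 171392794 in MN1-FLI1 replicate 1 (80.2 Mb, -0.58) and from 90687913 to 121963234 in HOXB9 replicate 1 (31.3 Mb, -0.46). The stretch common to these 4 leukemias was 91233666 to 119936545, or 28.7 Mb. Chromosome 6 was gained as a whole in GATA2-HOXA9 replicate 2 (median 0.48) and replicate 3 (0.29). Chromosome 13 was gained in MN1-FLI1 replicate 1 (median 0.26), mainly from 83547227 to 120276149. Chromosome 3 was lost from 132376927 to 154449349 in GATA2-HOXA9 replicate 4 (22.1 Mb, -0.87). At a median of at least 0.15 in size over a chromosome, 5 calls were made in the 23 arrays, 3 gains and 2 losses. The 2 losses are the partial chromosome 2 losses given above, in GATA2-HOXA9 replicate 2 and MN1-FLI1 replicate 1. No MN1 or NIPBL-HOXB9 array had such a call. No test was made of these calls, which describe single leukemias.

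**Figure D2:**
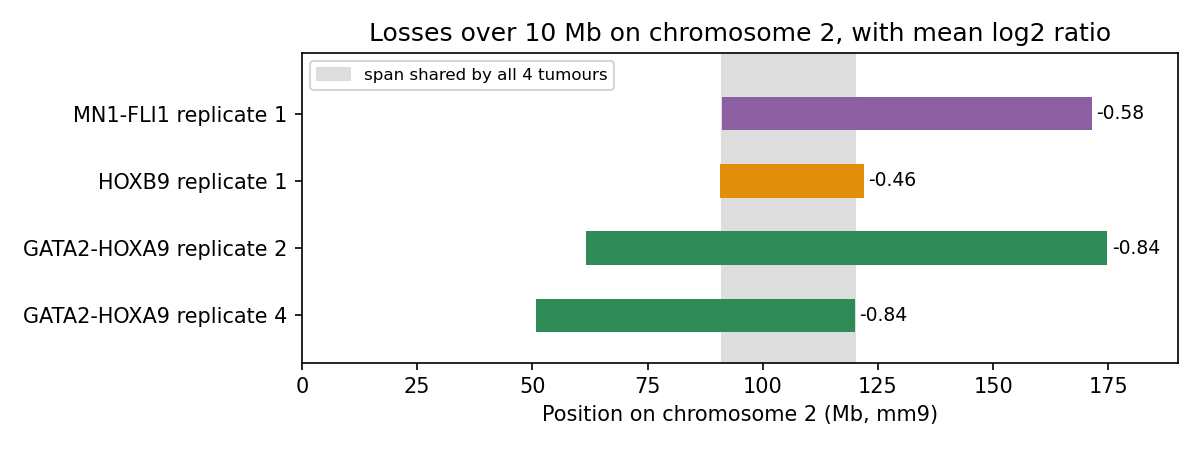
Losses of over 10 Mb on chromosome 2, drawn to scale along the mm9 position in Mb (x axis), 1 bar per leukemia, with the mean log2 ratio at the right of each bar. The grey band marks the 28.7 Mb that all 4 leukemias share.

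Smaller changes were also seen in few arrays. The reference was mixed-sex or male marrow and is not known to come from the same mouse. An inherited difference thus cannot be told from one acquired in the leukemia, here or in the segment counts below. On chromosome 19, NIPBL-HOXB9 replicate 1 had a gain from 37308063 to 37445522 (mean log2 ratio 0.65), and replicate 5 had one from 37313577 to 37439971 (0.59). The other 21 arrays lay between 0.01 and 0.17 over the first of these stretches. HOXB9 replicate 2 lost 106034974 to 106252215 on chromosome 9 (-0.68), and the 22 other arrays lay between -0.05 and 0.11 there. GATA2-HOXA9 replicate 2 lost 150190028 to 150327606 (-0.81) and 169463650 to 169537757 (-0.60) on chromosome 1. HOXB9 replicate 1 gained 115318915 to 115419788 on chromosome 7 (0.40). MN1-FLI1 replicate 4 lost 34750295 to 34782438 on chromosome 17 (-0.41). The array with the highest noise, MN1-FLI1 replicate 1, had short losses on chromosomes 7, 8, 11 and 19.

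Each group of 5 was compared with its reference marrow over 23629 windows of 100 kb, since the probes carry no gene names. Windows at 114700001 to 114800000 on chromosome 12 were higher in all 4 groups. Their mean log2 ratio was 0.71 ± 0.05 in MN1, 0.74 ± 0.05 in NIPBL-HOXB9, 0.73 ± 0.03 in GATA2-HOXA9 and 0.66 ± 0.09 in MN1-FLI1 (SD, n = 5; limma adjusted p 3.1e-13, 1.5e-13, 2.2e-13 and 1.6e-12). On chromosome 14, the window from 54700001 was higher by 0.47 ± 0.04 in MN1, 0.41 ± 0.07 in NIPBL-HOXB9, 0.35 ± 0.05 in GATA2-HOXA9 and 0.32 ± 0.15 in MN1-FLI1. On chromosome 6, the window from 41200001 was higher by 0.33 ± 0.03 in MN1, 0.27 ± 0.06 in NIPBL-HOXB9, 0.48 ± 0.17 in GATA2-HOXA9 and 0.31 ± 0.12 in MN1-FLI1. Both windows passed the threshold in all 4 groups. At the chromosome 6 window the GATA2-HOXA9 arrays ran from 0.30 to 0.73. They include replicates 2 and 3, with the gain of the whole chromosome given above. Segments of gain covered 114670169 to 116719861 on chromosome 12 and 54178846 to 54826763 on chromosome 14 in 23 of 23 arrays. Segments covered 40827263 to 41492582 on chromosome 6 in 13 arrays. Losses shared by many arrays lay at 3026911 to 3100205 on chromosome 11 (16 arrays), and on chromosome 12 at 17769385 to 20816555 (16 arrays) and 22857105 to 25076573 (13 arrays). The probes of these 3 regions had median reference signals of 28.2, 3.09 and 6.34 times the array median.

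In MN1, 48 windows were higher and 382 lower. The lowest of them, from 5900001 on chromosome 14 (-1.03), holds 1 probe and was lower in all 4 groups. NIPBL-HOXB9 had 95 higher and 134 lower. The window from 68600001 on chromosome 5 was higher by 0.42 in NIPBL-HOXB9, and by 0.23 in MN1-FLI1. MN1-FLI1 had 31 higher and 141 lower. GATA2-HOXA9 had 422 higher and 789 lower, of which 396 higher windows lay on chromosome 6 and 670 lower windows on chromosome 2. The window from 95100001 on chromosome 2 stood at -0.58 ± 0.44 (SD, n = 5), and the arrays ranged from -1.10 to -0.18. These are the chromosomes with large changes in single GATA2-HOXA9 leukemias. Across the 4 groups, 25 windows were higher and 42 lower in every group. With a fit on its own arrays alone, GATA2-HOXA9 had 43 windows past the threshold in place of 1211, and without replicate 2 it had 440. With scan day as a block the counts were 991 in MN1 and 769 in NIPBL-HOXB9. MN1-FLI1 had 96 on its own arrays alone, in place of 172. Without bright probes, whose reference signal was over 2 times the array median, there were 54 higher and 242 lower windows in MN1, 76 and 77 in NIPBL-HOXB9, 430 and 743 in GATA2-HOXA9, and 33 and 44 in MN1-FLI1. The normexp background correction gave 2109 higher and 2534 lower windows in MN1, 257 and 104 in NIPBL-HOXB9, 946 and 744 in GATA2-HOXA9, and 57 and 62 in MN1-FLI1.

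The fusions were then set against their single-gene counterparts, to ask which changes come with the fusion. MN1-FLI1 differed from MN1 in 1 window, on chromosome 5 from 146200001 to 146300000. It was at 0.00 ± 0.03 in MN1-FLI1 (SD, n = 5) and at -0.51 in MN1, a difference of 0.51 ± 0.07 (SE; limma adjusted p 0.0084). Of the 11 probes in this window, 2 belong to 9 probes at which MN1 replicates 1, 2, 4 and 5 lay below -1 and at least 0.5 below each other array. An unadjusted p under 0.05 was found in 2808 windows. The scan days do not overlap for these groups, as every MN1 array was scanned on day 1 and no MN1-FLI1 array was. With scan day as a block the count was 0. With normexp it was 187 windows, a count that does not say whether the chromosome 5 window is among them.

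NIPBL-HOXB9 and the 2 HOXB9 arrays differed in 0 windows by limma, with 1327 at an unadjusted p under 0.05. HOXB9 replicate 1 had the chromosome 2 loss described above, which no NIPBL-HOXB9 array had. Without HOXB9 replicate 1 the count was 15, with 1 HOXB9 array left, so that the spread came from the other groups. Without HOXB9 replicate 2 it was 1. MN1-FLI1 and the single FLI1 array differed in 20 windows, 6 higher and 14 lower, with 2402 at an unadjusted p under 0.05. The farthest were on chromosome 10 from 11200001 (-0.66) and on chromosome 4 from 144300001 (0.56). The FLI1 array is a single sample and is taken to vary like the others, so these windows describe that array. Single spots weigh in them: the window on chromosome 15 from 41500001 (0.30) holds A_67_P08347589, at -7.85 in the FLI1 array, and that on chromosome 12 from 65600001 (-0.45) holds A_67_P07644455, at 5.91. With the median of the probes of each window, or with only the arrays of both groups, 0 windows passed by limma (2209 and 964 at an unadjusted p under 0.05). Without spots marked by the scanner software as outlying, saturated or near background, 4 windows passed the threshold, and the chromosome 10 window stood at 0.17.

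The fusions were compared with one another, to find what they share and what is particular to each. GATA2-HOXA9 and NIPBL-HOXB9 differed in 0 windows by limma, with 4151 at an unadjusted p under 0.05. GATA2-HOXA9 and MN1-FLI1 differed in 0 windows by limma, with 3056 at an unadjusted p under 0.05. NIPBL-HOXB9 was higher than MN1-FLI1 from 30600001 to 30700000 on chromosome 9, by 0.20 ± 0.04 (SE; limma adjusted p 0.034). It was lower from 19600001 to 19700000 on chromosome 17, at -0.26 ± 0.05 (adjusted p 0.032). Against the reference, all 5 NIPBL-HOXB9 arrays lay above 0 at the first window (0.15 to 0.35) and below 0 at the second (-0.25 to -0.06). The MN1-FLI1 means there were 0.02 and 0.10. The moderated F-test over the 3 fusions passed 7 windows. It passed 0 with normexp, with the median of the probes, when centred on the mode and with only the arrays of these groups. With the mixed-sex reference only it passed 17. With scan day as a block, GATA2-HOXA9 differed from NIPBL-HOXB9 in 1898 windows and the F-test passed 1182, and the difference of NIPBL-HOXB9 and MN1-FLI1 passed in 0. GATA2-HOXA9 and NIPBL-HOXB9 overlap within days as 1 and 4 arrays on day 1 and 3 and 1 on day 2. The GATA2-HOXA9 array of day 1 is replicate 2, with the large changes of chromosomes 2 and 6, and day 1 alone gave 2663 windows and day 2 alone 0.

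The number of changed segments per leukemia was compared, to ask whether one transgene leaves more altered genomes. There were 22.4 ± 10.69 segments in MN1, 1.0 ± 0.71 in NIPBL-HOXB9, 9.6 ± 7.0 in GATA2-HOXA9 and 12 ± 10.3 in MN1-FLI1 (SD, n = 5). The HOXB9 arrays had 18 and 3, and the FLI1 array 11. A permutation test over the 4 groups gave p = 0.0063. MN1 exceeded NIPBL-HOXB9 by 21.4 segments (exact permutation test, two-sided, p = 0.0079, Benjamini-Hochberg adjusted over 6 pairs 0.048). Within scan day 1 the difference was 21.4 too, with 4 NIPBL-HOXB9 arrays (exact permutation p = 0.016). The adjusted p rose to 0.095 with normexp, 0.119 at a segment height of 0.15 and 0.524 with a running median. With the mixed-sex reference alone it was 0.095 too, while the difference stayed at 21.4. That setting leaves 4 NIPBL-HOXB9 arrays and fewer splits, so its higher p does not show a weaker difference. The adjusted p was 0.0794 to 0.0952 when any one MN1 or NIPBL-HOXB9 array was left out, which also leaves fewer splits. MN1 minus GATA2-HOXA9 was 12.8 segments (adjusted p 0.0794). Joining neighbouring segments lowered the mean of GATA2-HOXA9 to 4.2, as replicate 4 went from 19 to 3, and this difference to MN1 became 18 (adjusted p 0.0238). It also passed with at least 5 probes and with common segments kept (both 0.048), and was -4.4 without bright segments (0.405). The counts include 15 pieces of the chromosome 12 gain that 23 of 23 arrays share, in 12 arrays, among them the only segment of NIPBL-HOXB9 replicate 2. Without these pieces the means were 22 in MN1, 0.6 in NIPBL-HOXB9, 8.4 in GATA2-HOXA9 and 11.2 in MN1-FLI1, and MN1 minus NIPBL-HOXB9 stayed at 21.4 (adjusted p 0.048). Of the 257 segments, 167 lay in bright probes, and MN1 held 14 to 31 of these per array. Without them the means were 3.2 in MN1, 0.8 in NIPBL-HOXB9, 7.6 in GATA2-HOXA9 and 4.4 in MN1-FLI1, and the permutation test over the 4 groups gave p = 0.16. MN1 minus NIPBL-HOXB9 was then 2.4 segments (adjusted p 0.405), and 11.2 (adjusted p 0.048) with bright probes set at over 3 times. The choice of the factor 2, and the removal itself, were made after the shared losses had been seen.

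**Figure D3:**
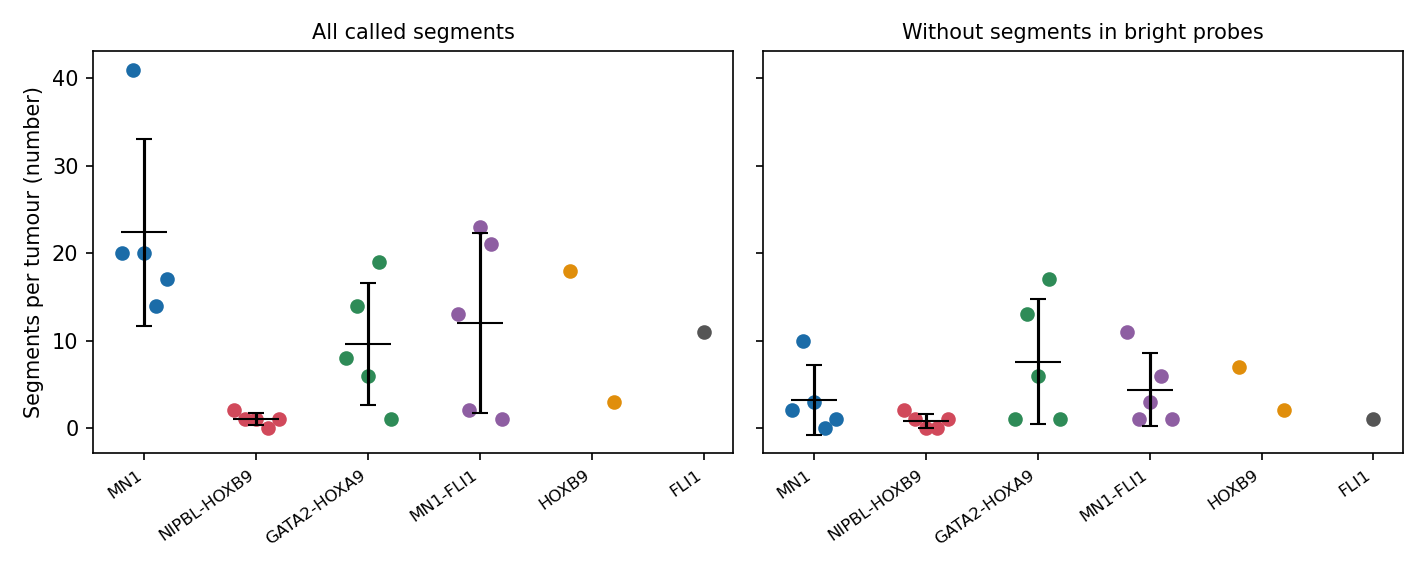
Called segments per leukemia (y axis), 1 point per array, by group (x axis). The left panel has all segments and the right panel those outside bright probes, and black bars give the mean and SD of the groups of 5. MN1 has a mean of 22.4 on the left and 3.2 on the right.

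The share of the autosomes altered was 4.21% ± 4.42 in GATA2-HOXA9, 1.21% ± 2.06 in MN1-FLI1, 0.603% ± 0.288 in MN1 and 0.0256% ± 0.0314 in NIPBL-HOXB9 (SD, n = 5). It reached 10.73% in GATA2-HOXA9 replicate 2, which carried the chromosome 2 loss and the chromosome 6 gain. In MN1-FLI1 replicate 1 it was 4.87%, and in HOXB9 replicate 1 it was 1.84%. A permutation test over the 4 groups of 5 gave p = 0.051. In exact permutation tests NIPBL-HOXB9 minus GATA2-HOXA9 was -4.18 points (p = 0.016, adjusted 0.048), and MN1 minus NIPBL-HOXB9 was 0.578 points (p = 0.0079, adjusted 0.048). Without the pieces of the chromosome 12 gain, NIPBL-HOXB9 minus GATA2-HOXA9 was -4.17 points (adjusted p 0.143). Without bright segments MN1 minus NIPBL-HOXB9 was 0.121 points (adjusted p 0.19). Within scan day 1, with all segments, it was 0.576 points (exact permutation p = 0.016), and GATA2-HOXA9 and NIPBL-HOXB9 share too few arrays of a day. Both adjusted values passed the threshold narrowly, and both rose to 0.05 or above under several settings given in the closing part.

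Single probes were tested for the human transgenes, whose cDNA can bind mouse exonic probes, as a check of the labels. The clearest was A_67_P02969297 on chromosome 15 from 8316680 to 8316739, higher in NIPBL-HOXB9 by 1.07 ± 0.09 (SE; limma adjusted p 2.3e-06). It was 1.31 ± 0.26 in the 5 NIPBL-HOXB9 arrays (SD, lowest 1.00) and 0.24 ± 0.16 in the 18 others (highest 0.52). Mouse Nipbl lies on chromosome 15 in the GRCm38 gene table, and the probe was not matched to the gene here. In all, 2834 of 382487 probes passed for NIPBL, 13 for MN1, 54 for FLI1, 7 for HOXB9 and 1 for GATA2 and HOXA9. The first probe for HOXB9 was the same A_67_P02969297, and its lowest value in an array with HOXB9 was 0.07, within the range of the arrays without it. The counts depend on single arrays. HOXB9 had 1 when NIPBL-HOXB9 replicate 1, 2 or 5 or the FLI1 array was left out, and 2297 without MN1-FLI1 replicate 5. GATA2 and HOXA9 had 0 without GATA2-HOXA9 replicate 2, HOXB9 replicate 2 or the FLI1 array, 1990 without GATA2-HOXA9 replicate 1, and 5118 with scan day as a block. The NIPBL count was 1 without NIPBL-HOXB9 replicate 2 and 5286 without MN1-FLI1 replicate 1. For MN1 and FLI1 the first probe was A_67_P08347589 on chromosome 15, whose lowest value, -7.85, was that of the single FLI1 array, and both counts were 0 without that array.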

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

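All tests of explanations in this part were chosen after the results were seen. A far sample was sought in 114 groups of values, and 11 were found, while chance gives about 1 in 20. Dixon's ratio was 0.778 for the segments of MN1 replicate 2 (41, against 14 to 20) and 0.954 for its altered share (1.12%). It was 0.898 for the X median of MN1 replicate 3 and 0.969 for its Y median, and 0.881 for the altered share of MN1-FLI1 replicate 1. Among windows it was 0.776 on chromosome 14 from 54700001 in MN1 replicate 4, and in GATA2-HOXA9 replicate 2 it was 0.759 on chromosome 2 from 138700001 and 0.8004 on chromosome 7 from 24000001. In MN1-FLI1 it was 0.742 on chromosome 15 from 41500001 (replicate 2) and 0.839 on chromosome 2 from 33700001 (replicate 1), and in NIPBL-HOXB9 replicate 2 it was 0.712 on chromosome 9 from 30600001.

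Groups differed by test in 6 results. MN1-FLI1 exceeded MN1 by 0.51 on chromosome 5 from 146200001. As many windows as the real 1 came in 2 of 100 splits, of 126 possible, with the real split among the 2. The highest other split had 1 too, so few splits reach this count, but a chance division is not excluded. Nor is scan day, since it parts these groups wholly. The count was 0 with scan day as a block, with only the arrays of both groups and without marked spots. It was also 0 with the mixed-sex reference only and without MN1 replicate 2. In other settings, given in the closing part, it was higher. NIPBL-HOXB9 exceeded MN1-FLI1 by 0.20 on chromosome 9 from 30600001 and lay at -0.26 on chromosome 17 from 19600001. Here 3 of 100 splits gave as many windows as the real 2, and the highest other gave 4. The F-test over the 3 fusions gave 7 windows, with 2 of 100 splits as large and 14 in the highest. GATA2-HOXA9 against NIPBL-HOXB9 had 0 windows in the real split and 0 in the highest other, and GATA2-HOXA9 against MN1-FLI1 had 0. With a real count of 0 each of the 100 splits is as large by construction, so the splits decide nothing for these 2 comparisons. The highest split of the latter gave 176 windows and joined GATA2-HOXA9 replicates 1 to 4 with MN1-FLI1 replicate 1, with 147 of them on chromosome 2 and 29 on chromosome 6. This points to a structure of the samples: MN1-FLI1 replicate 1 and GATA2-HOXA9 replicates 2 and 4 have losses on chromosome 2, and GATA2-HOXA9 replicates 2 and 3 have gains on chromosome 6. MN1 exceeded NIPBL-HOXB9 by 21.4 segments and by 0.578 points of altered share, and NIPBL-HOXB9 minus GATA2-HOXA9 was -4.18 points.

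Losses in bright probes were most frequent in MN1, with 14 to 31 segments per array. Scan day alone does not account for them, as the other 5 arrays of day 1 held at most 1. These 5 arrays had red over green signals of 0.94 to 1.52, below the lowest MN1 ratio of 1.63. A day effect at higher ratios is thus not excluded. MN1 in the transgene does not account for the losses alone, since HOXB9 replicate 1 had 11 without MN1 and MN1-FLI1 replicate 5 had 0 with it. The bright segments rose with the red over green signal of the array, also over the 18 arrays other than MN1. There Pearson r was 0.61 (permutation p 0.0077), Spearman rho 0.76 (permutation p 4e-04), and r 0.71 without the 2 farthest arrays. Of the 6 other arrays at or above the lowest MN1 ratio, 4 held over 5 bright segments, while GATA2-HOXA9 replicate 4 held 2 and MN1-FLI1 replicate 2 held 1. A candidate explanation is therefore the signal balance of the array, and the biology of MN1 stays open within it, since MN1 arrays have high ratios.

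The Y chromosome was raised in 7 arrays labelled female: 0.91, 0.82, 0.89 and 0.85 in MN1 replicates 1, 2, 4 and 5, 0.41 in GATA2-HOXA9 replicate 3, 0.65 in MN1-FLI1 replicate 3 and 0.90 in the FLI1 array. X was not raised in 4 more arrays labelled female, over a male reference: 0.0292 in NIPBL-HOXB9 replicate 2, -0.0176 in GATA2-HOXA9 replicate 1, 0.0169 in GATA2-HOXA9 replicate 4 and 0.0553 in HOXB9 replicate 1. In the 7 arrays the Y signal of the Cy3 channel was 0.311 to 0.335 of its autosomal signal, as in the 10 arrays with a raised X (0.307 to 0.331). An exchange of the channels would put it near the 0.0596 to 0.0968 that Cy5 had in those 10 arrays, which argues against it. Male cells in the sample may account for the pattern, since the Y signal of Cy5 was at least 0.385 in the 7 arrays. In the 4 arrays over a male reference it was 0.498, 0.458, 0.0515 and 0.369, in the order above. In GATA2-HOXA9 replicate 4 it thus lay below that of the arrays with a raised X, while its X signal was 0.472, and male cells that keep their Y do not account for this array. With normexp, which also lacks the lowess and spatial steps, the Y medians of the 7 arrays were -0.63 to -0.14. The sign of the Y ratio thus differed between normexp and the main processing. Relative to the autosomes, the background-subtracted Y signal of these 7 arrays was higher in Cy5 (0.385 to 0.479) than in Cy3 (0.311 to 0.335). Their X medians with normexp were -0.78 to -0.21. Normexp also lowered MN1-FLI1 replicate 2, labelled male over a male reference, to -0.22 for X and -0.21 for Y. The X median of GATA2-HOXA9 replicate 3 with normexp, -0.21, was thus no lower than that of this array. Whether the label is wrong or the marrow donor was male was not tested.

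MN1 replicates 1, 2, 4 and 5, of these 7 arrays, share 9 autosomal probes (-1.39 to -4.58), each at least 0.5 lower in them than in any other array, though other arrays reached -1.61. All 9 fell in 1 of 8855 possible sets of 4 arrays. Arrays on the same slides reached -0.70, but the probes were chosen for lying lower in the 4 arrays than in all others, so this decides nothing on a slide effect, which stays open. The lowest median of the neighbouring probes was 0.0876 on chromosome 4 and -0.0625 for 4 of the 5 probes on chromosome 2, which argues against a longer deletion at these 6 probes. At the other probe on chromosome 2 it was -0.37, and on chromosome 5 it was -0.50, within the spread of those probes from -0.5, so a short deletion stays open there. A sequence or donor shared by these animals is consistent with the 9 probes, as a hypothesis.

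Gains on chromosomes 12, 14 and 6 appeared across the groups. On chromosome 12, 97.3% of 255 probes lay above 0, against 66.4% in the flanks, so the gain is spread over most of its probes. The region was called as a gain in these same values, so this share decides nothing on a dye bias. The reference signal relative to the flanks was at most 0.711 on chromosome 12, 0.836 on chromosome 14 and 0.895 on chromosome 6. The sample signal lay below the flanks on average too, at 0.886, 0.963 and 0.962, each by more than its SD over the arrays (0.0338, 0.0259 and 0.035). Fewer copies in the reference marrow, as in rearranged lymphocytes, is a candidate explanation, and a different response of these probes stays open on all 3 chromosomes. No antigen receptor test was run, and no biological explanation by transgene was tested.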

How the results depend on the processing

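The bright-probe settings, the other window sizes, the scan-day subsets, the scan-day block for transgene probes, the joined segments, the removal of pieces of common regions and the sets without arrays whose X goes against the label were tests chosen after the data were seen, and the bright threshold was moved from 3 to 2 times the array median after a look at the shared losses. Of 95 named windows, 6 kept their call in every setting run, and 15 of the values turned sign. The deposited value table left all 11 window counts within 1.5 times the main ones. The GC correction, the gene lists and the antigen receptor loci were not run, as the files pair no probe with a gene and no genome of their build was used here. Low red signal, at 62.2 in MN1-FLI1 replicate 1, limits what that array can show. Below, counts of windows are for each group against the reference unless a comparison is named. The causes of these changes were not tested, except where fewer arrays, another threshold or another window size changes the count by construction.

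With normexp background correction, the windows numbered 4643 for MN1, 361 for NIPBL-HOXB9, 187 for MN1-FLI1 against MN1, 9 for MN1-FLI1 against FLI1, 0 for NIPBL-HOXB9 against MN1-FLI1 and 0 for the F-test. The permutation p over the 4 groups was 0.192 for segments. The difference in segments was 67.6 for MN1 minus NIPBL-HOXB9. In percent altered, the difference was 4.7 for MN1 minus NIPBL-HOXB9, 0.685 for MN1 minus GATA2-HOXA9, 3.77 for MN1 minus MN1-FLI1 and -4.01 for NIPBL-HOXB9 minus GATA2-HOXA9. The transgene probes numbered 760 for MN1, 35 for FLI1, 387 for NIPBL and 3 for HOXB9. The mean log2 ratio there became 0.14 on chromosome 1 from 119900001 (MN1 against reference), 0.0282 on chromosome 7 from 21800001 (GATA2-HOXA9 against reference) and 0.00405 on chromosome 4 from 146400001 (GATA2-HOXA9 against reference). In windows of 50 kb, the windows numbered 1721 for MN1, 1237 for NIPBL-HOXB9, 2423 for GATA2-HOXA9, 588 for MN1-FLI1, 4 for MN1-FLI1 against MN1, 69 for MN1-FLI1 against FLI1 and 0 for the F-test. In windows of 500 kb, the windows numbered 59 for MN1, 31 for NIPBL-HOXB9, 260 for GATA2-HOXA9, 40 for MN1-FLI1, 0 for MN1-FLI1 against FLI1, 0 for NIPBL-HOXB9 against MN1-FLI1 and 94 for the F-test. At a size floor of 0.1, the windows numbered 4142 for MN1, 4169 for NIPBL-HOXB9, 2885 for GATA2-HOXA9, 1860 for MN1-FLI1, 2 for MN1-FLI1 against MN1 and 24 for NIPBL-HOXB9 against MN1-FLI1. At a size floor of 0.3, the windows numbered 178 for MN1, 46 for NIPBL-HOXB9, 580 for GATA2-HOXA9, 91 for MN1-FLI1, 13 for MN1-FLI1 against FLI1 and 0 for NIPBL-HOXB9 against MN1-FLI1. With no size floor, the windows numbered 9492 for MN1, 9725 for NIPBL-HOXB9, 6339 for GATA2-HOXA9, 5290 for MN1-FLI1, 2 for MN1-FLI1 against MN1 and 25 for NIPBL-HOXB9 against MN1-FLI1. With scan day as a block, the windows numbered 991 for MN1, 769 for NIPBL-HOXB9, 0 for MN1-FLI1 against MN1, 9 for MN1-FLI1 against FLI1, 1898 for GATA2-HOXA9 against NIPBL-HOXB9, 0 for NIPBL-HOXB9 against MN1-FLI1 and 1182 for the F-test. The transgene probes numbered 6 for MN1, 15 for FLI1, 5118 for GATA2 and HOXA9 and 11 for HOXB9. Without the 11 arrays whose X goes against the label, which leaves 1 MN1, 1 HOXB9 and 2 GATA2-HOXA9 arrays, the windows numbered 126 for MN1, 21 for GATA2-HOXA9, 0 for MN1-FLI1 against MN1, 6 for NIPBL-HOXB9 against HOXB9, 0 for NIPBL-HOXB9 against MN1-FLI1 and 0 for the F-test. The altered percent differed by -5.35 for NIPBL-HOXB9 minus GATA2-HOXA9. On scan day 2 only, with 1 array each for NIPBL-HOXB9, HOXB9 and FLI1, the windows numbered 0 for NIPBL-HOXB9, 17 for GATA2-HOXA9, 75 for MN1-FLI1, 0 for MN1-FLI1 against FLI1, 0 for NIPBL-HOXB9 against MN1-FLI1 and 0 for the F-test. With only the arrays of the groups compared, the windows numbered 43 for GATA2-HOXA9, 96 for MN1-FLI1, 0 for MN1-FLI1 against MN1, 0 for MN1-FLI1 against FLI1, 0 for NIPBL-HOXB9 against MN1-FLI1 and 0 for the F-test. Without the 7 arrays with a lowered X, which leaves 1 MN1 array, the windows numbered 529 for GATA2-HOXA9, 0 for MN1-FLI1 against MN1, 0 for NIPBL-HOXB9 against MN1-FLI1 and 0 for the F-test. Segments differed by 1.25 for GATA2-HOXA9 minus MN1-FLI1. In percent altered, the difference was -3.71 for NIPBL-HOXB9 minus GATA2-HOXA9. On scan day 1 only, with 1 GATA2-HOXA9 array, replicate 2, the windows numbered 2728 for GATA2-HOXA9 and 2663 for GATA2-HOXA9 against NIPBL-HOXB9. In windows with at least 3 probes, the windows numbered 90 for MN1-FLI1. Without bright probes, the windows numbered 77 for MN1-FLI1 and 4 for the F-test. The mean log2 ratio there became -0.022 on chromosome 13 from 80200001 (NIPBL-HOXB9 against reference), 0.23 on chromosome 10 from 11200001 (MN1-FLI1 against FLI1) and 0.00968 on chromosome 7 from 111400001 (MN1-FLI1 against FLI1). Without bright probes at 3 times, meaning a reference signal over 3 times the array median, the windows numbered 94 for MN1-FLI1, 11 for MN1-FLI1 against FLI1 and 3 for the F-test. The mean log2 ratio there became -0.022 on chromosome 13 from 80200001 (NIPBL-HOXB9 against reference) and 0.23 on chromosome 10 from 11200001 (MN1-FLI1 against FLI1). Without spots marked on any array, the windows numbered 0 for MN1-FLI1 against MN1, 4 for MN1-FLI1 against FLI1, 0 for NIPBL-HOXB9 against MN1-FLI1 and 2 for the F-test. The mean log2 ratio there became -0.00645 on chromosome 4 from 144300001 (MN1-FLI1 against FLI1), -0.11 on chromosome 15 from 41500001 (MN1-FLI1 against FLI1), 0.17 on chromosome 10 from 11200001 (MN1-FLI1 against FLI1) and 0.10 on chromosome 1 from 130600001 (MN1-FLI1 against FLI1). With the median of the probes, the windows numbered 2 for MN1-FLI1 against MN1, 0 for MN1-FLI1 against FLI1, 1 for NIPBL-HOXB9 against MN1-FLI1 and 0 for the F-test. The mean log2 ratio there became -0.00477 on chromosome 13 from 80200001 (NIPBL-HOXB9 against reference), 0.12 on chromosome 10 from 11200001 (MN1-FLI1 against FLI1) and 0.043 on chromosome 14 from 99100001 (MN1-FLI1 against FLI1). With the kind of reference as a block, the windows numbered 2 for MN1-FLI1 against MN1, 10 for MN1-FLI1 against FLI1 and 4 for GATA2-HOXA9 against NIPBL-HOXB9. The transgene probes numbered 5 for MN1, 3 for GATA2 and HOXA9 and 4 for HOXB9. With the mixed-sex reference only, the windows numbered 0 for MN1-FLI1 against MN1, 11 for NIPBL-HOXB9 against HOXB9, 4 for MN1-FLI1 against FLI1, 145 for GATA2-HOXA9 against NIPBL-HOXB9, 17 for GATA2-HOXA9 against MN1-FLI1, 0 for NIPBL-HOXB9 against MN1-FLI1 and 17 for the F-test. The permutation p over the 4 groups was 0.0302 for altered share. The difference in segments was 21.4 for MN1 minus NIPBL-HOXB9. The altered percent differed by 0.576 for MN1 minus NIPBL-HOXB9 and -5.59 for NIPBL-HOXB9 minus GATA2-HOXA9. With slide as a random block, the windows numbered 2 for MN1-FLI1 against MN1. With array weights, the windows numbered 2 for MN1-FLI1 against MN1 and 44 for MN1-FLI1 against FLI1. With a replicate block, the windows numbered 1 for NIPBL-HOXB9 against HOXB9, 1 for GATA2-HOXA9 against NIPBL-HOXB9, 0 for NIPBL-HOXB9 against MN1-FLI1 and 1 for the F-test. When centred on the mode, the windows numbered 13 for MN1-FLI1 against FLI1, 0 for NIPBL-HOXB9 against MN1-FLI1 and 0 for the F-test. When centred on all probes, the windows numbered 1 for the F-test. With at least 20 probes, the permutation p over the 4 groups was 0.0626 for segments. With a running median, the permutation p over the 4 groups was 0.814 for segments. Segments differed by 40.6 for MN1 minus NIPBL-HOXB9, -3.8 for MN1 minus GATA2-HOXA9 and -78.2 for MN1 minus MN1-FLI1. In percent altered, the difference was 0.612 for MN1 minus NIPBL-HOXB9 and -3.68 for NIPBL-HOXB9 minus GATA2-HOXA9. Without bright segments, the permutation p over the 4 groups was 0.16 for segments. The difference in segments was 2.4 for MN1 minus NIPBL-HOXB9, -4.4 for MN1 minus GATA2-HOXA9, -1.2 for MN1 minus MN1-FLI1 and 3.2 for GATA2-HOXA9 minus MN1-FLI1. The altered percent differed by 0.121 for MN1 minus NIPBL-HOXB9 and -4.12 for NIPBL-HOXB9 minus GATA2-HOXA9. Without bright segments, at 3 times, the permutation p over the 4 groups was 0.0947 for segments. Segments differed by 1.8 for GATA2-HOXA9 minus MN1-FLI1. At a height of 0.15, the difference in segments was 23.4 for MN1 minus NIPBL-HOXB9. In percent altered, the difference was 0.418 for MN1 minus NIPBL-HOXB9 and -3.42 for NIPBL-HOXB9 minus GATA2-HOXA9. With at least 5 probes, the difference in segments was 19.8 for MN1 minus GATA2-HOXA9. With common segments kept, the difference in segments was 14.8 for MN1 minus GATA2-HOXA9. The altered percent differed by -4.17 for NIPBL-HOXB9 minus GATA2-HOXA9. With neighbouring segments joined, the difference in segments was 18 for MN1 minus GATA2-HOXA9, which was 12.8 in the report. Joining, at least 5 probes and common segments kept each took the adjusted p of this difference below 0.05. Without pieces of common regions, NIPBL-HOXB9 minus GATA2-HOXA9 in altered percent was -4.17, with an adjusted p of 0.143. At a height of 0.35, the difference in percent altered was -2.94 for NIPBL-HOXB9 minus GATA2-HOXA9.

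The replicate numbers did not pair the arrays: the mean correlation of same-numbered deviations ran from -0.08 to 0.02 over the 6 pairs of groups. The replicate block is therefore given here only, as counts of windows past the threshold. The slide as a random block had a correlation of -0.0465. Over the settings, the adjusted p of MN1 minus NIPBL-HOXB9 in segments ran from 0.0159 to 0.524, that of the altered percent from 0.0159 to 0.648, and that of NIPBL-HOXB9 minus GATA2-HOXA9 in altered percent from 0.0318 to 0.571. Leaving out arrays also leaves fewer splits. A group left with 1 array takes its spread from the other groups, so its counts describe that array.

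Each array was also left out in turn, and the values below are the extremes. Windows of GATA2-HOXA9 ran from 440 (without GATA2-HOXA9 replicate 2) to 1752 (without GATA2-HOXA9 replicate 5). Windows of MN1-FLI1 against MN1 ran from 0 (without MN1 replicate 2) to 3 (without MN1 replicate 3). Windows of NIPBL-HOXB9 against HOXB9 ran from 0 (without NIPBL-HOXB9 replicate 1) to 15 (without HOXB9 replicate 1, leaving 1 HOXB9 array). Windows of MN1-FLI1 against FLI1 ran from 7 (without MN1-FLI1 replicate 2) to 30 (without MN1-FLI1 replicate 1). Windows of GATA2-HOXA9 against NIPBL-HOXB9 ran from 0 (without NIPBL-HOXB9 replicate 1) to 94 (without GATA2-HOXA9 replicate 1). Windows of NIPBL-HOXB9 against MN1-FLI1 ran from 0 (without NIPBL-HOXB9 replicate 1) to 13 (without MN1-FLI1 replicate 5). Windows of the F-test ran from 0 (without NIPBL-HOXB9 replicate 1) to 41 (without MN1-FLI1 replicate 5). The p for the altered share ran from 0.00954 (without GATA2-HOXA9 replicate 5) to 0.0966 (without GATA2-HOXA9 replicate 2). Segment differences of MN1 minus NIPBL-HOXB9 ran from 16.8 (without MN1 replicate 2) to 23.5 (without MN1 replicate 4). Segment differences of NIPBL-HOXB9 minus GATA2-HOXA9 ran from -10.8 (without GATA2-HOXA9 replicate 5) to -6.25 (without GATA2-HOXA9 replicate 4). Segment differences of GATA2-HOXA9 minus MN1-FLI1 ran from -5.15 (without MN1-FLI1 replicate 5) to 0.35 (without MN1-FLI1 replicate 3). Altered percent differences of MN1 minus NIPBL-HOXB9 ran from 0.449 (without MN1 replicate 2) to 0.614 (without MN1 replicate 1). Altered percent differences of MN1 minus MN1-FLI1 ran from -0.899 (without MN1-FLI1 replicate 5) to 0.312 (without MN1-FLI1 replicate 1). Altered percent differences of NIPBL-HOXB9 minus GATA2-HOXA9 ran from -5.23 (without GATA2-HOXA9 replicate 5) to -2.55 (without GATA2-HOXA9 replicate 2). Altered percent differences of NIPBL-HOXB9 minus MN1-FLI1 ran from -1.48 (without MN1-FLI1 replicate 5) to -0.266 (without MN1-FLI1 replicate 1). Probes for MN1 ran from 0 (without FLI1 replicate 1) to 1113 (without MN1-FLI1 replicate 1). Probes for FLI1 ran from 0 (without FLI1 replicate 1) to 91 (without MN1-FLI1 replicate 1). Probes for GATA2 and HOXA9 ran from 0 (without GATA2-HOXA9 replicate 2) to 1990 (without GATA2-HOXA9 replicate 1). Probes for NIPBL ran from 1 (without NIPBL-HOXB9 replicate 2) to 5286 (without MN1-FLI1 replicate 1). Probes for HOXB9 ran from 1 (without NIPBL-HOXB9 replicate 1) to 2297 (without MN1-FLI1 replicate 5).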

Other observations

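The tests and values in this part were chosen after the data were seen. On chromosome 12, MN1-FLI1 replicate 4 had the lowest mean over the common gain, 0.33, and the arrays reached 0.55. On chromosome 6 the array values, which include the whole-chromosome gains of GATA2-HOXA9 replicates 2 and 3, ran from 0.14 to 0.65. On chromosome 14 they ran from 0.22 to 0.42, with the lowest in NIPBL-HOXB9 replicate 2. Of the 9 probes low in 4 MN1 arrays, 5 lay on chromosome 2 between 104514839 and 119854851, a span of 15.3 Mb, and 2 on chromosome 5 within the window that separated MN1-FLI1 from MN1. GATA2-HOXA9 replicate 1 alone had a loss from 53390194 to 53961747 on chromosome 14, at -0.47, and the 22 other arrays lay between -0.17 and 0.07.

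The relation of bright segments with red over green signal was also taken within scan days. Over the 10 arrays of day 2, none of them MN1, Pearson r was 0.73 (permutation p 0.015), Spearman rho 0.74 (permutation p 0.019), and r 0.84 without the 2 farthest. Over the 10 arrays of day 1 r was 0.90 (permutation p 6e-05), rho 0.95 (permutation p 0.00013), and r 0.91 without the 2 farthest. On day 1 the 5 MN1 arrays lay above the other 5 in both quantities, so these values mostly restate the difference of MN1 from the others. Over all 23 arrays r was 0.81 and rho 0.84, each with a permutation p of 1e-05, the smallest these permutations can give, and r was 0.75 without the 2 farthest. Scan day 3 holds too few arrays for a value. With the 18 arrays other than MN1 these relations make one family of 8 tests, and the Benjamini-Hochberg adjusted p ran from 4e-05 to 0.0187.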
